A study of Homo sapiens with 4 samples.

How the data were processed

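Drop-seq, a droplet method that tags each captured messenger RNA with a cell barcode and a molecular identifier, was used on dissociated kidney organoids, per the labels' protocols. The series design text names a 10x Genomics platform instead, and the barcodes in the files have 12 bases. Each protocol lists about 20 organoids per condition, a cold-active protease at 4°C and about 100000 cells loaded per group. For the Day 9 samples, at the nephron progenitor stage, about 200000 cells were isolated under deprivation and about 500000 under the standard condition. At that day this difference goes along with the medium, and no such number is given for the Day 23 samples. Differentiation used CHIR99021 at 8 µM for 4 days, activin A at 10 ng/mL for 3 days and then FGF9 at 10 ng/mL, per the labels' protocols. The labels give 1 library for each of 4 groups, glutamine-deprived and standard medium at Day 9 and at Day 23.

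The deposited tables hold whole-number molecule counts per gene symbol and cell barcode, with 3000 barcodes per table. Reads were paired at 26 and 115 bp with the barcode in read 1, per the labels' protocols. Seurat and the GRCh38 build are listed in the submitters' processing notes without a version or a role. The aligner, the annotation, the handling of reads shared between genes and the rule that chose 3000 barcodes are not given in the sources used here. No table names its sample, so tables were assigned by the day and the code in each table's name, C1 or C2, which matches a single sample title each. C1 is the deprived and C2 the standard condition in those titles.

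Symbols were joined over the 4 tables, which gave 34415, of which 24164 matched GENCODE release 29 (GRCh38). Gene types and coordinates come from that match, and 58 symbols (Y-linked genes, XIST and TSIX) were left out of every reported result. Cells with at least 500 detected genes and at most 25% of counts from mitochondrially encoded genes were kept. The Day 23 standard table had 2455 barcodes under 500 genes, with a median of 138 counts per barcode over all its barcodes, and so gives the least precise values. Counts were summed over the kept cells of each library, to 5621946, 4788604, 5702809 and 979164 for Day 9 deprived, Day 9 standard, Day 23 deprived and Day 23 standard. Ratios were taken between CPM scaled by TMM factors (trimmed by 30% on ratios and 5% on levels) for genes with a mean of at least 10 CPM. The factors equalled those of edgeR 4.0.16. Exact conditional binomial (Clopper-Pearson) 95% intervals cover counting error only, and a count of 0 was replaced by a floor of 3 counts, which makes the ratio a bound. Ratios were taken over 10361 genes at Day 9, 10661 at Day 23, and 10820 and 10420 between days in standard and deprived medium.

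Before the data were examined, 41 gene lists (23 of pathways and 18 of cell types), the markers that name clusters, the cell filter and the rule for named genes were fixed. A list member counted as higher or lower at a ratio of at least 1.25 with an interval that leaves out 1. List medians carry an order-statistic 95% interval over members and a percentile among 10000 lists matched in 20 expression bins. Genes were ranked by the interval bound nearest to 0. The text names the 10 highest and 10 lowest between media, the 6 highest and 6 lowest between days, up to 2 highest and 2 lowest members of each list described, and up to 3 of each within a cluster. Mitochondrially encoded, ribosomal protein and clone-named genes were left out of the rankings over all genes. A gene that the rule gave for the deprived medium between days was left unnamed because its copy number can differ between people. Some genes given by the rule are not reported here. The 8 genes of the plot of levels were chosen for display after their values were seen.

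Cells of the 2 libraries of each day were clustered together without integration (scanpy 1.11.5; 10000 counts per cell, log scale, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8, fixed seed). A cluster was called X-like with at least 3 of a class's markers among its top 50 genes and at least 2 times those of any other class, unless its top 10 held more markers of another class. After the data were seen, a cluster with PAX3, PAX7, MYF5, MYF6 or MSC among its top 10 genes was barred from the nephron progenitor name. Scrublet marked 12 of 9244 cells as doublets, too few for a working call, so doublets stayed in, and an alternative without the 5% highest doublet scores was added afterwards. Shares carry exact binomial intervals. Ratios within clusters were taken where both libraries had at least 50 cells.

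The ratio and list steps were tested on simulated counts, first run after the main ratios had been computed. These counts held counting noise only, around a single averaged profile of each pair of libraries. They therefore check the computation, and not the spread between replicates or the scaling under a large change in cell mixture. At simulated log2 changes of 1, 2, -1 and -2, all of the changed genes were recovered at Day 9, where intervals held the true ratio for 95.1% of genes. At Day 23, 86% of genes with a log2 change of -1 and all at the other sizes were recovered. Between days, 92% were recovered at -1 in standard medium. Alternatives covered the scaling (plain CPM, median centring), the expression filter, the cell filter, equal weight per cell, doublets, cluster resolution, clustering per library and thinning. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and scikit-learn 1.9.0, with plots by matplotlib 3.10.9.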

Results

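Droplet-based single-cell transcriptomes were collected from kidney organoids that the labels describe as grown from H9, a human embryonic stem cell line. Organoids were differentiated either in standard medium, which contained a stabilised glutamine dipeptide, or under glutamine deprivation. Glutamine feeds nitrogen into amino acid and nucleotide synthesis and carbon into the tricarboxylic acid cycle, and the series asks how its removal alters metabolic gene expression during kidney differentiation. Each medium was represented by 1 library labelled Day 9 and 1 library labelled Day 23, which makes 4 libraries with no replicate of any group. Each deposited table held 3000 cell barcodes. The summed molecule counts were 5682792 for the deprived library labelled Day 9, 4864348 for the standard library labelled Day 9, 5815455 for the deprived library labelled Day 23 and 1366362 for the standard library labelled Day 23. After removal of barcodes with under 500 detected genes or over 25% mitochondrial counts, 2954, 2926, 2819 and 545 cells remained in the same order, with a median of 1556.5, 1198.5, 1455 and 1397 counts per cell.

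Because each group had 1 library, no difference between groups could be set against a replicate spread and no test was made. Intervals on ratios and shares are 95% limits that cover counting error only. A list of genes is given by the median log2 ratio of its members minus the median of all measured genes. Its percentile was taken among 10000 random lists of the same size matched on expression, which describes these libraries and not the conditions. Day names are those of the labels, since a check for mixed-up samples found that 2 of the 4 libraries did not match the labelled line.

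The comparison of media at Day 9 asked which genes differ between the libraries with that label. These libraries held podocyte-like, muscle-like and neuron-like cells, as described below, so the label is not read here as an early stage. Genes of the podocyte, the cell that forms the filtration slits of the glomerulus, were lower in the deprived library. The receptor tyrosine phosphatase PTPRO was at 85.6 CPM in the deprived and 405 CPM in the standard library, 4.73-fold lower (log2 ratio -2.24, interval -2.39 to -2.10, 483 and 1935 counts). Of the 24 measured podocyte genes, 20 were lower and 1, THSD7A, was higher, with a list median of -1.50 at percentile 0. The nephron progenitor list, led downward by WT1 (log2 ratio -1.60) and PAX8 (-1.27), had a median of -0.94, with 12 of 16 members lower and 3 higher. WT1 also belongs to the podocyte list, so these lists are not independent of each other. The proximal tubule list, with SLC34A1 (-1.93) and SLC3A1 (-1.69), had a median of -1.34 and 8 of 9 members lower. PTPRO lies on chromosome 12 at 15322397 to 15597399 (GRCh38).

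Outside the podocyte list, the metallothionein genes MT1H, MT1G and MT1E, whose products bind zinc and copper, were lower in the deprived library at Day 9, at log2 ratios of -4.09, -3.50 and -3.01. These genes are close copies of each other on chromosome 16, and how reads shared between them were counted is not given in the sources used here. AFP, which encodes the fetal plasma protein alpha-fetoprotein, was 8.33-fold lower, and the immediate early gene FOS was 7.45-fold lower (76 and 479 counts). CA10, the small leucine-rich proteoglycan gene OGN and the receptor gene MRGPRF were 7.96-fold, 5.72-fold and 6.64-fold lower.

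Among the highest ratios at Day 9 was that of SLN, which encodes sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum. It was 79.8-fold higher in the deprived library (377 and 4 counts, log2 ratio 6.32, interval 4.95 to 8.20). The secretory granule genes CHGB and CHGA were 17.5-fold and 12.0-fold higher. DLK1, a membrane protein of mesenchymal progenitors, was at 1277 CPM against 140 CPM (log2 ratio 3.19, interval 3.08 to 3.31). CALB1, ABI3BP, LHX9 and IGSF10 were 16.5-fold, 15.9-fold, 11.4-fold and 7.46-fold higher. Among lists, that of neurons had a median of 0.82 with 13 of 15 members higher, STMN2 among them (log2 ratio 2.09). That of neural crest had a median of 1.16, with TFAP2B (1.92) and S100B (1.69) highest and PAX3 lower (-1.55). SLN lies on chromosome 11 at 107707378 to 107719693 and DLK1 on chromosome 14 at 100725705 to 100738224.

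Metabolic lists moved apart at Day 9. Cytosolic ribosomal protein genes, which supply the translation machinery, were higher in the deprived library, with a list median of 0.48, 47 of 81 members higher and 3 lower, at percentile 100. RPS29 (log2 ratio 0.85) and RPL35 (0.78) were highest, while RPL4 (-0.37) and RPLP0 (-0.36) were lowest. Nuclear-encoded respiratory chain genes had a median of 0.24 at percentile 100, with 22 of 71 members higher, such as ATP5I (0.96) and NDUFA3 (1.16), and 11 lower, such as ATP5A1 (-0.61) and ATP5F1 (-0.57). The respiratory chain genes of the mitochondrial genome went the other way, with a median of -0.37 at percentile 0.885. MT-ND1 (-1.08) and MT-CYB (-0.95) were lowest, and MT-ND3 (0.30) was highest.

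Tricarboxylic acid cycle genes had a median of -0.37 at Day 9, with 16 of 23 members lower and 0 higher, led by SDHD (log2 ratio -0.85) and MDH1 (-0.63). Cholesterol and fatty acid synthesis genes had a median of -0.40 at percentile 0, with the sterol regulator INSIG1 (-1.10) and IDI1 (-0.94) lowest and STARD4 (0.62) highest. Lysosome and autophagy genes had a median of -0.32, with GRN (-0.80) and LAMP2 (-0.83) lowest. Glycolysis genes had a median of -0.28, with SLC16A1 (-0.76) and PGAM1 (-0.75) lower and ENO2 (1.13) higher. Genes of glutamine and glutamate metabolism had a median of -0.18 at percentile 4.53, with GLUD1 (-0.79) and GOT2 (-0.64) lowest. Targets of ATF4, the transcription factor of the amino acid response, had a median of -0.15 at percentile 13.1, with PCK2 (-1.22) and ATF4 itself (-0.56) lower and DDIT4 (0.71) and DDIT3 (0.53) higher. Extracellular matrix genes had a median of 0.28, with COL1A2 (1.14) and COL1A1 highest and SPARC (-0.80) lowest.

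**Figure D1:**
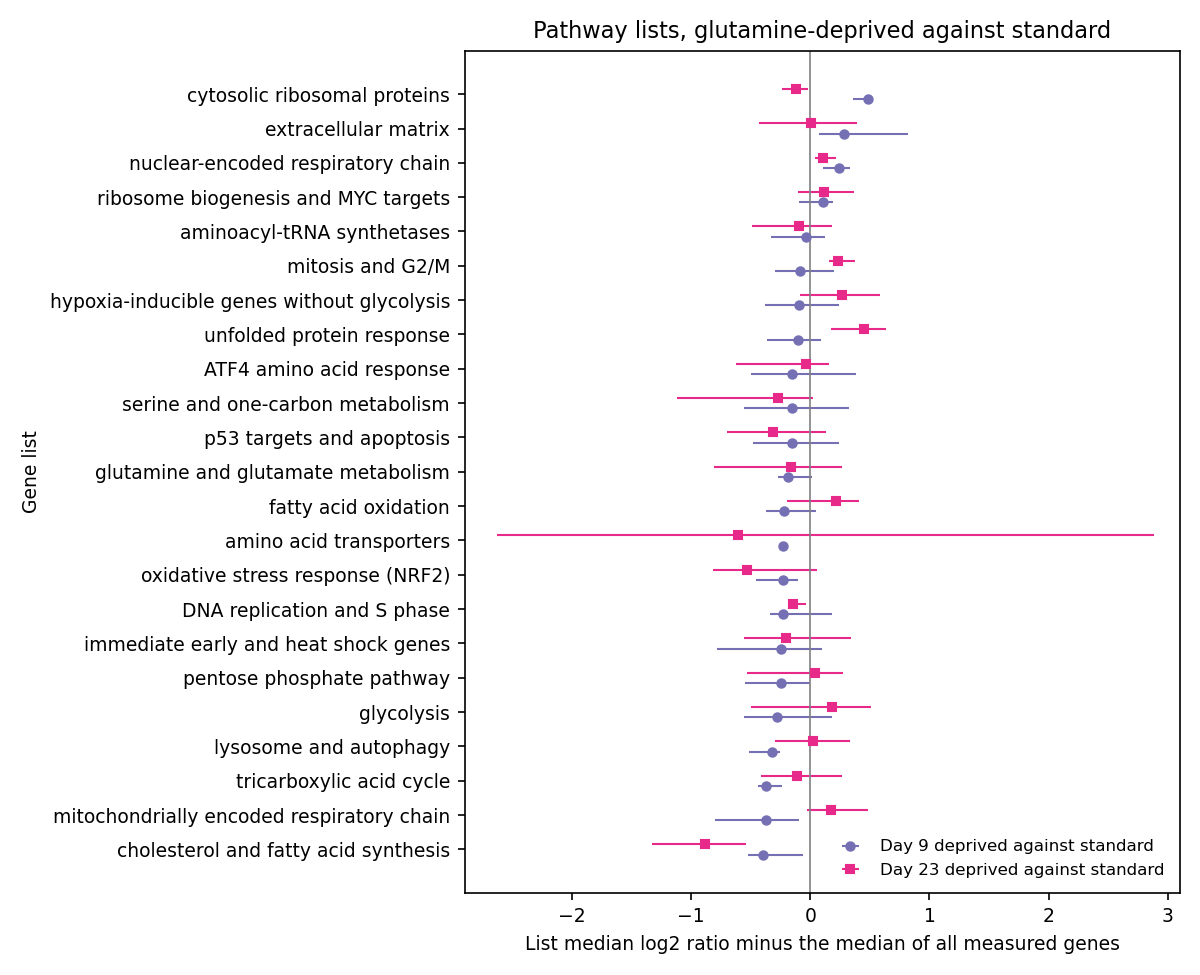
Median log2 ratio of each pathway list, deprived against standard medium, minus the median of all measured genes, on the horizontal axis for Day 9 (circles) and Day 23 (squares), with 1 library per group; bars are 95% order-statistic intervals of the median over members and are absent for the list with 5 members at Day 9. The ribosomal protein list lay at 0.48 at Day 9 and -0.12 at Day 23, and the cholesterol and fatty acid synthesis list lay at -0.40 and -0.88.

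Clustering of the Day 9 cells gave 12 clusters. The podocyte-like cluster, with PTPRO, SOST and PODXL among its leading genes, held 3.62% of the deprived cells (107 of 2954, exact interval 2.98 to 4.36%) and 15.5% of the standard cells (454 of 2926, 14.2 to 16.9%). With each library clustered alone, the podocyte-like shares were 4.74% and 7.25%. A neural crest-like cluster with TFAP2B among its leading genes held 11.1% and 2.49%, and a stroma-like cluster led by ACTA2, ACTG2 and TAGLN held 7.52% and 24.5%. An unnamed cluster led by DLK1, SLN, ELMOD1 and CALB1 held 48.7% of the deprived and 2.43% of the standard cells, and with 1 library per group it cannot be separated from a property of that library. Skeletal muscle-like cells, with MYL1 and ACTC1, made up 0.846% and 1.98%, and neuron-like cells, with NEUROD1 and STMN2, made up 2.27% and 1.16%. An unnamed cluster with SIM2, PAX3 and MYF6 among its leading genes held 3.25% and 13.3%. PAX3 was counted in 19.1% of its cells. A rule set after the data were seen kept this cluster out of the nephron progenitor class. NPHS1 was counted in 78.5% and 71.6% of podocyte-like cells (median 1776 and 1248 counts per cell) and in 1.33% and 4.17% of other cells (median 1547 and 1183.5).

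**Figure D2:**
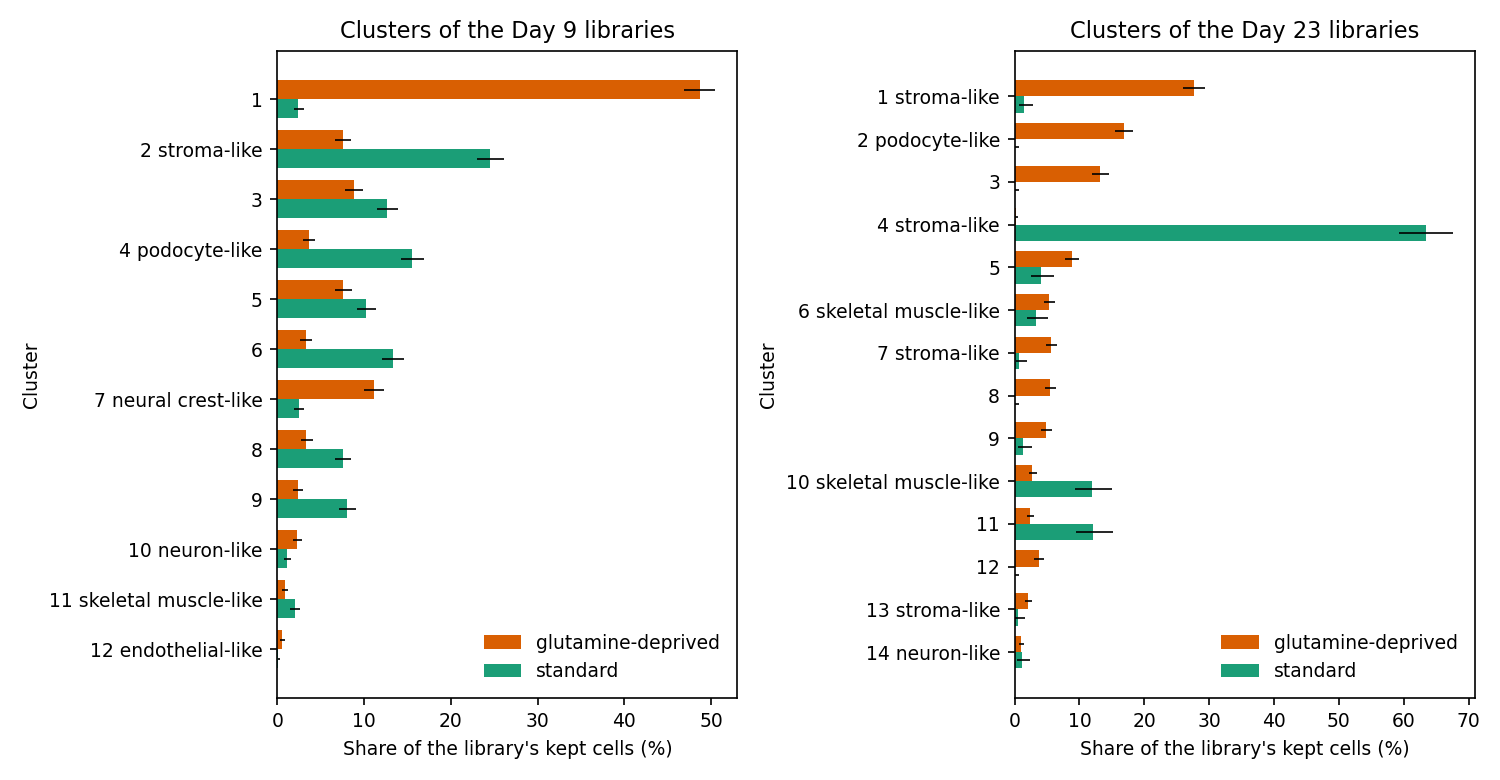
Share of each library's kept cells (percent) in each cluster of Day 9 and Day 23, deprived libraries in orange and standard libraries in green, with exact 95% binomial intervals. The podocyte-like cluster held 3.62% of deprived and 15.5% of standard cells at Day 9, and 16.8% of deprived and 0 of 545 standard cells at Day 23.

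Within clusters, the question was whether the list differences remained once the mixture of cells varied less than in whole libraries. Clusters do not hold it fully constant. An unnamed cluster with TOP2A and MKI67 among its leading genes had 0 cell type markers in its top 50 and may pool several cell types. In each of the 9 Day 9 clusters with at least 50 cells per library, ribosomal protein genes lay above all genes, by 0.33 to 0.56 and at percentile 100. Nuclear-encoded respiratory chain genes also lay above all genes in 9 of 9 clusters, by 0.03 to 0.39, with the lowest cluster at percentile 84.2, and at percentile 34.1 with cells thinned to equal depth (lowest value 0.02). Fatty acid oxidation genes (-0.33 to -0.14) and lysosome genes (-0.32 to -0.06) lay below in 9 of 9. Pentose phosphate pathway genes also lay below in 9 of 9 (-0.38 to -0.06), but in 6 of 9 with cells thinned to equal depth. The mitochondrially encoded chain lay below in 9 of 9, by -0.51 to -0.10, but in 8 of 9 with cells thinned to equal depth, where the highest value was 0.24. Other lists did not keep a single direction. Clusters above and below all genes numbered 1 and 8 for the tricarboxylic acid cycle and for cholesterol and fatty acid synthesis. They numbered 4 and 5 for glycolysis, 3 and 6 for glutamine and glutamate metabolism, and 8 and 1 for extracellular matrix. At a mean of at least 50 CPM, the tricarboxylic acid cycle lay below all genes in 9 of 9. In the podocyte-like cluster, the podocyte list differed by -0.06 between media. That cluster was itself named from this list, so the small value cannot show whether the difference in podocyte genes remained within cells. There the ATF4 targets had a median of 0.72 at percentile 99.99, but 0.34 at percentile 86.3 with cells thinned to equal depth and 0.18 at percentile 77.8 at a mean of at least 50 CPM. DDIT3 (log2 ratio 2.62, 67 and 32 counts), CEBPB (2.82) and the asparagine synthetase gene ASNS (1.96) were the highest genes named there, and FOS was lowest (-4.42, 2 and 126 counts). The ATF4 list was above all genes in 2 of the 9 clusters and below in 6.

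**Figure D3:**
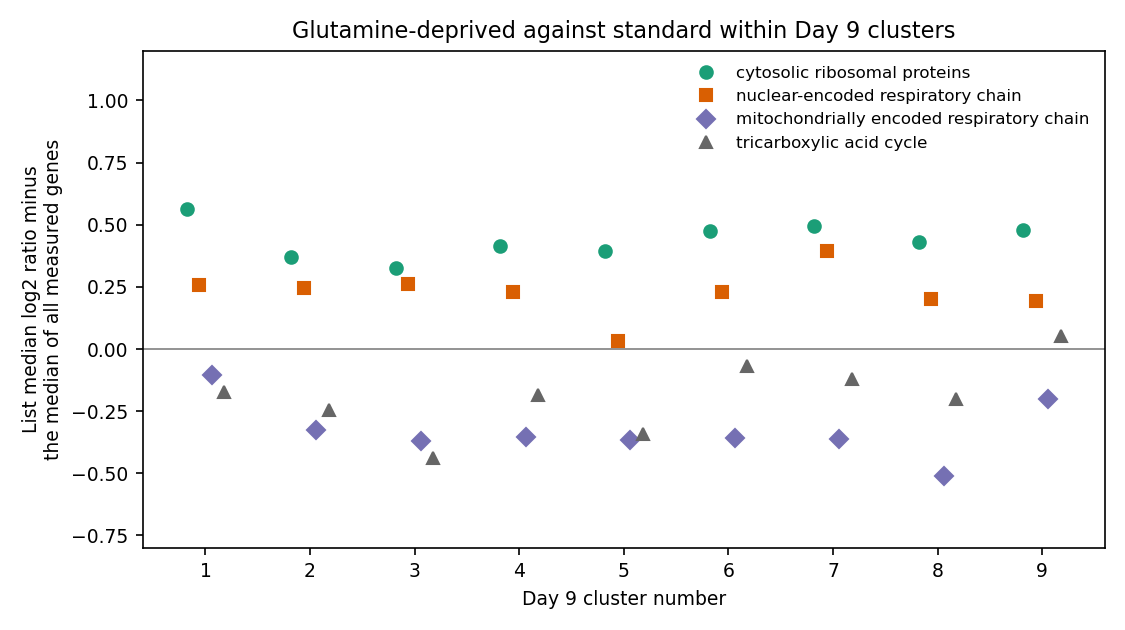
Median log2 ratio of 4 lists, deprived against standard, minus the median of all measured genes (vertical axis), for each Day 9 cluster with at least 50 cells in both libraries (horizontal axis, cluster number); each symbol is a list in a cluster. The ribosomal protein list ranged from 0.33 to 0.56 and the mitochondrially encoded respiratory chain list from -0.51 to -0.10.

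At Day 23, the comparison of media asked about the same genes in the libraries with that label, and podocyte genes were higher in the deprived library. CLIC5, a podocyte foot process protein gene, was at 812 CPM in the deprived library and 0.931 CPM in the standard library (4218 and 1 counts, log2 ratio 9.77, interval 7.29 to 15.07). NPHS1, which encodes nephrin, had 2420 and 1 counts (8.97, interval 6.49 to 14.27) and PODXL had 4047 and 3 (8.12, interval 6.58 to 10.40). PTPRO (6.41), the neprilysin gene MME (6.75) and SOST (5.81) were also higher, as were CXCL14 (7.75), ENPEP (6.54) and ANXA1 (6.24), for which the standard library had 3 counts each. Of 24 podocyte genes, 23 were higher and 0 lower, with a list median of 4.35. The early nephron list had a median of 1.02, with 7 of 12 members higher and 2 lower (WNT4 and PAX8 highest). For proximal tubule the median was 1.16, with 7 of 11 higher and 0 lower (GPX3 and CUBN highest). Loop of Henle genes had a median of 1.44, with 8 of 11 higher and 1 lower, SLC12A1 lowest at a log2 ratio of -3.73. The order-statistic intervals of these list medians included 0. CLIC5 lies on chromosome 6 at 45880827 to 46080348 and NPHS1 on chromosome 19 at 35825964 to 35869287.

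Among the lowest ratios at Day 23, LUM, which encodes the matrix proteoglycan lumican, was 71.0-fold lower (15 and 220 counts, log2 ratio -6.15, interval -7.01 to -5.40). The cartilage collagen gene COL2A1 was 25.5-fold lower, FAM150B 24.0-fold lower, FIBIN 23.3-fold lower and ITM2A 21.0-fold lower. The lists of extracellular matrix (11 of 30 members higher and 9 lower, median 0.01), stroma (8 of 24 higher and 8 lower, median -0.17) and cartilage (1 of 7 higher and 2 lower, median -0.20) had members in both directions. The skeletal muscle list had a median of -1.97, with 17 of 18 members lower, led by the troponin genes TNNC1 (log2 ratio -2.98) and TNNC2 (-2.37). The neuron list had a median of -1.21, with DCX (-1.86) lower and SYT1 (1.22) highest. The neural crest list had a median of -1.50, with PAX3 (-3.80) lowest. The remaining lowest ratios belonged to the processed pseudogenes EEF1A1P9, EEF1A1P11, HSPA8P5, EEF1A1P6 and EEF1A1P13, 13.7-fold to 22.6-fold lower. Processed pseudogenes can take reads from their parent genes, and they held 3.37% of counts in the deprived and 6.77% in the standard library.

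TMM scaling moved all ratios at Day 23 by 0.27 against plain CPM, so lists are given relative to all genes. Cholesterol and fatty acid synthesis genes had a median of -0.88 at percentile 0, with FDFT1 (log2 ratio -1.56) lower and ELOVL6 (0.76) highest. Genes of the unfolded protein response, which expands protein folding in the endoplasmic reticulum, had a median of 0.45 at percentile 98.9, with PDIA3 (1.35) and CANX (1.11) highest. Mitosis genes had a median of 0.24 at percentile 97.2, with KIF23 (1.22) and ECT2 (1.35) highest, and an unnamed cluster with TOP2A and MKI67 held 8.80% of deprived and 4.04% of standard cells. NRF2 targets had a median of -0.53 at percentile 0.210, with the cystine transporter gene SLC7A11 (-1.88) and AKR1C1 (-1.88) lowest. Nuclear-encoded respiratory chain genes had a median of 0.11 at percentile 42.4, led by COX6C (0.94) and NDUFA13 (1.08). The mitochondrially encoded chain had a median of 0.17 at percentile 71.5, with MT-ND4L (1.04) highest, and its median ratio was -0.27 when every deposited barcode was used. The ribosomal protein list had a median of -0.12 at percentile 0.300, where the TMM ratio alone gave 0.10, with RPL7 (-1.63) and RPS3A (-1.13) lowest and RPL36 (1.41) highest.

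Some metabolic lists changed sign at Day 23 with the scaling, so each is given here relative to all genes and without that subtraction. Genes of glutamine and glutamate metabolism had a median of -0.16 relative to all genes and 0.05 without that subtraction, with PYCR1 (log2 ratio -1.12) and GPT2 (-1.22) lowest and PPAT (1.26) highest. ATF4 targets had -0.04 and 0.17, with STC2 (-1.42) and DDIT4 (-1.13) lowest and ATF3 (0.76) highest. Tricarboxylic acid cycle genes had -0.11 and 0.10, with SUCLG1 (0.90) highest. Serine and one-carbon genes had -0.27 and -0.05, with PSAT1 (-1.10) and SHMT2 (-0.90) lowest. Amino acid transporter genes had -0.60 and -0.39 at percentile 2.75, with 3 of 8 members higher, SLC7A8 (3.09) and SLC3A2 (0.69) among them, and 3 lower, SLC1A3 (-2.42) and SLC7A11 (-1.88) among them. Glycolysis genes had 0.18 and 0.39, with the glucose transporter genes SLC2A1 (2.33) and SLC2A3 (1.29) highest and PGAM1 (-1.02) lowest.

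Clustering of the Day 23 cells gave 14 clusters, few of which held cells of both libraries in number. The podocyte-like cluster, led by CXCL14, PODXL and SOST, held 16.8% of deprived cells (474 of 2819, exact interval 15.5 to 18.2%) and 0 of 545 standard cells, which allows a share of up to 0.550% by the limit of 3 counts and 0.675% by the exact interval. NPHS1 was counted in 85.0% of podocyte-like cells, in 9.42% of other deprived cells and in 0.183% of standard cells, at medians of 1351, 1482 and 1397 counts per cell. Skeletal muscle-like cells, from a cluster with MYL1 and MYH3 and another with PAX7 and MYF6, made up 8.05% of deprived and 15.2% of standard cells, and the standard share ranged from 11.9% to 24.8% under other clusterings. Stroma-like cells made up 35.7% and 66.2%, but mostly from different clusters: that led by INHBA and CPED1 held 780 deprived and 8 standard cells, and that led by ITM2A and LUM held 8 deprived and 346 standard cells. The processed pseudogenes EEF1A1P11 and EEF1A1P6 were also among the leading genes of the ITM2A and LUM cluster. Processed pseudogenes held 3.37% of all deprived and 6.77% of all standard counts. With 1 library per group, this split of stroma-like cells cannot be separated from a property of the libraries. Unnamed clusters led by SHISA3 and BMPER, by the immediate early genes FOSB and FOS, and by PCP4 and DAPL1 held 13.2%, 5.50% and 3.69% of deprived cells and 0 of 545 standard cells.

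The Day 23 clusters with at least 50 cells per library were the skeletal muscle-like cluster with MYL1 (77 and 65 cells) and an unnamed cluster with MSX1 and COL2A1 (67 and 66 cells). In the skeletal muscle-like cluster, aminoacyl-tRNA synthetase genes had a median of 0.63 at percentile 99.67, but -0.01 at percentile 67.1 with cells thinned to equal depth. ATF4 targets had a median of 0.33 there. KDM3A (log2 ratio 2.53, interval 1.03 to 4.50) and the ATF4 target TRIB3 (2.48, interval 0.74 to 4.87) were among the highest genes. RPL7 (-1.74) and RPS3A (-0.95) were among the lowest there, although the ribosomal protein list as a whole had 19 members higher and 5 lower. In the unnamed cluster, PPP1R15A (2.53) and JUN (1.78) were highest, and mitosis genes had a median of -0.90. Over the 2 clusters, the ribosomal protein list lay above all genes, at 0.11 and 0.20, unlike in the whole libraries, but at -0.05 and 0.09 with cells thinned to equal depth. The unfolded protein response list lay at 0 and 0.21 in these 2 clusters, below its whole-library value of 0.45. They held only 77 and 67 of the 2819 deprived cells. Whether the mixture of cells accounts for the whole-library value therefore cannot be told.

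The comparison of Day 23 with Day 9 within each medium asked which genes differ between the labelled days, and in these libraries day, run and source of cells could not be separated. The imprinted transcript H19, which is abundant in fetal tissues, had 2173 counts in the standard and 10901 in the deprived library labelled Day 23, and 0 in both libraries labelled Day 9, which makes it at least 2899-fold and at least 3738-fold higher. CHCHD2, which encodes a mitochondrial protein, had 361 and 1702 counts at Day 23 and 1 in each library at Day 9 (log2 ratio 10.50, interval 8.01 to 15.80, and 10.77, interval 8.29 to 16.08). The imprinted gene NNAT was higher in both media (10.88 and 8.71), as was TYW3, at least 80.1-fold and at least 154-fold. In standard medium FAM150B (9.17) and TMEM132C (at least 86.7-fold) were also among the highest, and in deprived medium CNTN4 (8.22) and FOSB (8.86). H19 lies on chromosome 11 at 1995176 to 2001470 and CHCHD2 on chromosome 7 at 56101569 to 56106576.

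In standard medium the lowest ratios of Day 23 to Day 9 belonged to podocyte genes, among them CLIC5 (log2 ratio -8.65), NPHS1 (-8.45), PODXL (-7.30) and OLFM3, which was at least 109-fold lower, beside the kallikrein gene KLK6, at least 52.6-fold lower. In deprived medium they belonged to SLN (-7.52, 2 and 377 counts), FRG1BP, FRG1CP, ZNF471 and ZNF667-AS1, which were at least 101-fold, 93.0-fold, 76.8-fold and 57.7-fold lower. FRG1BP and FRG1CP are copies of a repeated gene family, which leaves their counts uncertain. The podocyte list had a median of -3.59 in standard and 2.25 in deprived medium. The skeletal muscle list was higher at Day 23 in both media (3.16 and 1.96), led by MYH3 (4.90 and 2.97). Ribosomal protein genes (1.56 and 1.05, RPL39 highest at 3.51 and 2.96) and nuclear-encoded respiratory chain genes (0.97 and 0.86, with NDUFA1 at 2.34 and 2.36) were also higher in both. Fatty acid oxidation genes (-0.94 and -0.51) and glycolysis genes (-0.55 and -0.35), GAPDH (-1.55 and -0.49) and LDHB (-1.26 and -0.80) among them, were lower.

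**Figure D4:**
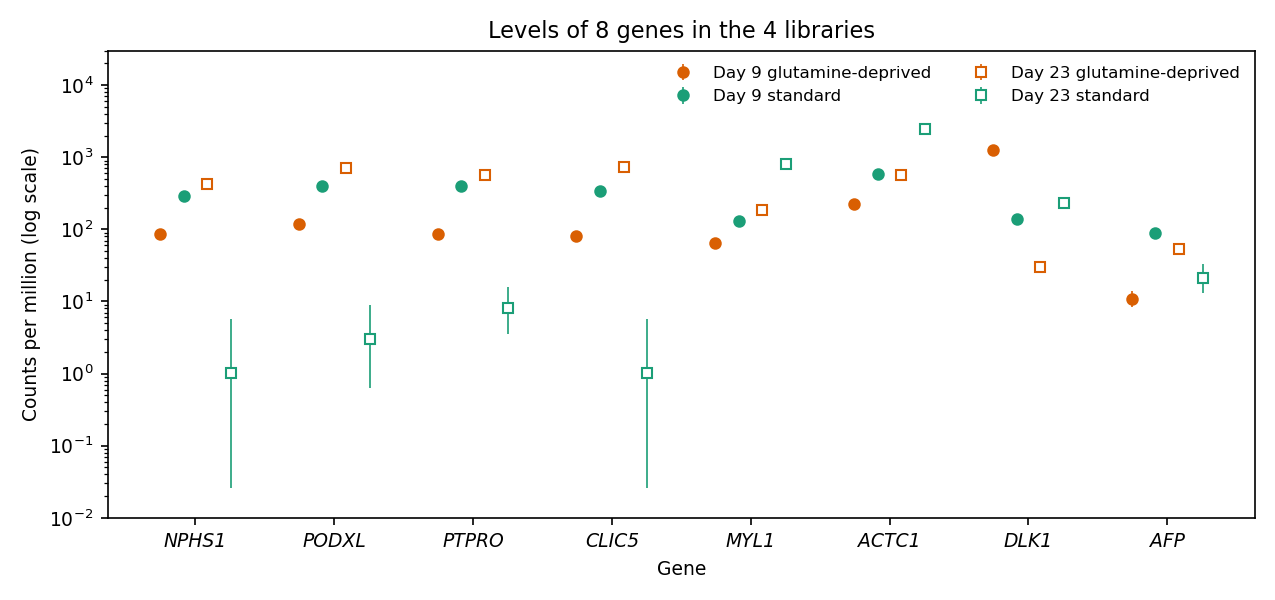
Plain CPM (log axis) of 8 genes in the 4 libraries, Day 9 as filled circles and Day 23 as open squares, deprived libraries in orange and standard libraries in green, with exact 95% counting intervals. NPHS1 was at 86.8 and 293 CPM in the deprived and standard libraries at Day 9, and at 424 and 1.02 CPM at Day 23.

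Ratios of deprived to standard medium at Day 9 and at Day 23 were weakly correlated across genes, with a Spearman correlation of 0.04 over 9510 genes (53.1% in the same direction) and 0.155 over the 3171 genes with a mean of at least 50 CPM (56.9%). Genes are not independent replicates, so no p-value is given. DLK1 was higher in the deprived library at Day 9 (log2 ratio 3.19) and lower at Day 23 (-2.67), and PTPRO, MT1G and MT1H went the opposite way.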

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

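The tests of exchanged labels and of cell mixture within clusters were chosen after the results were seen, those of thinned counts and removed barcodes were set before but rerun with 1 gene fewer afterwards, with the same outcome, and those of transcript length, GC content and nuclear RNA were chosen before. The match on length and GC content was redone with older gene symbols after a version that covered too few respiratory chain genes, at the same percentile.

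Several results had opposite signs between media at the 2 days, and in each case the difference was not tested, since each group has 1 library. The podocyte list stood at -1.50 at Day 9 and 4.35 at Day 23 relative to all genes, a difference of 5.85. The neuron list went from 0.82 to -1.21, a difference of -2.03. Neuron-like cells at Day 23 made up 0.993% of deprived (28 of 2819) and 1.10% of standard cells (6 of 545), with overlapping exact intervals. That list also holds neural progenitor genes, however. SOX2 and FABP7, members of it, were among the leading genes of the unnamed Day 23 cluster with MSX1 and COL2A1. This cluster held 2.38% of deprived and 12.1% of standard cells, so the list ratio is not independent of the shares of cells. The ribosomal protein list went from 0.48 to -0.12, a difference of -0.60. That last change of sign depends on the scaling, since the Day 23 ratio without the subtraction of all genes was 0.10, and the list lay at 0.11 and 0.20 within the 2 Day 23 clusters compared (-0.05 and 0.09 with cells thinned). Among named genes, the Day 23 log2 ratio minus the Day 9 log2 ratio was 11.84 for CLIC5, 10.73 for NPHS1, 9.85 for PODXL, 8.65 for PTPRO, 8.28 for MME and 8.02 for SOST. It was 9.42 for CXCL14, 8.51 for ENPEP, 7.86 for ANXA1, 7.92 for MRGPRF and 5.51 for CA10. The metallothionein genes MT1H, MT1G and MT1E gave 8.90, 8.58 and 7.85, and DLK1 gave -5.87. Of these genes, NPHS1, PODXL, PTPRO, CLIC5, MME and SOST belong to the podocyte list, so they are not independent of it. CXCL14 and ENPEP were among the leading genes of the podocyte-like cluster at both days. MT1H and MT1G were among those of an unnamed cluster with AFP. That cluster held 3.35% of deprived and 7.52% of standard cells at Day 9, and 4.90% and 1.28% at Day 23. The ratios of these genes are therefore not independent of the shares of cells.

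Podocyte genes were lower in the deprived library at Day 9 and higher in it at Day 23. Low depth per cell at Day 23 is argued against, since with every cell thinned to 500 counts, 14.7% of deprived cells (413 of 2819) and 0 of 545 standard cells had at least 3 counts of NPHS1, PODXL, PTPRO and CLIC5 together. Removal of podocyte-like cells by the cell filter is argued against as well, since these genes reached 25.8 CPM in the removed standard barcodes (upper limit 47.5) against 2441 CPM in all deprived barcodes. Exchanged labels at Day 23 cannot be told apart from a real change of direction, because the ratios of the 2 days correlated at a Spearman value of 0.05 (0.0472) outside cell type lists, between the bounds set for either case, although it was 0.172 at a mean of at least 50 CPM, above the bound of 0.1 for labels in place. An effect of glutamine that depends on the day, differences between single organoid batches, and another origin of cells than labelled, given 2 of 4 libraries that did not match the line, all stay open.

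The medians of the ribosomal protein and nuclear-encoded respiratory chain lists lay above that of all genes in the deprived library at Day 9, although 11 of the 71 measured genes of the chain were lower and 22 higher. Transcript length and GC content were taken from the longest annotated transcript of each gene. By that measure they are argued against as the whole cause, since both lists stayed at percentile 100 among genes matched on either property. Longer transcripts also had higher ratios (Spearman 0.28), while these lists hold short ones. The transcripts present in the cells can differ from the longest, and their own length and GC content were not tested. MALAT1 served as the measure of nuclear RNA. In cells with MALAT1 between 0.5% and 1.5% of counts (341 deprived and 1839 standard), the lists kept at least 160.5% of their relative medians. The differences were thus not reduced in these cells. Median MALAT1 was 3.27% of counts in deprived and 0.806% in standard cells, so the window left out most deprived cells. It therefore cannot decide whether the share of nuclear RNA plays a part. A mixture of cell types between clusters is argued against as the whole cause, since both lists lay above all genes in 9 of 9 clusters, but the nuclear-encoded chain was only 0.03 above in the lowest of them (0.02 with cells thinned), so mixture may account for part of its difference. Mixture within clusters was not held constant, as in the cluster with TOP2A and MKI67, and was not tested. Length, GC content and mixture between clusters are argued against only as the whole cause, and nuclear RNA and mixture within clusters stay undecided. Glutamine deprivation may contribute to these differences. That is a hypothesis that 1 library per medium cannot separate from a difference between library preparations.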

How the results depend on the processing

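Median centring, the removal of the highest doublet scores, a higher expression minimum within clusters and the restriction to genes in no cell type list were added after the data were seen, and the other settings were planned. No paired analysis was possible because each group has 1 library, with replicate number 2 at Day 9 and none given at Day 23, and leaving out a replicate was not possible for the same reason. List values here are median log2 ratios before the median of all genes is subtracted.

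Of the list medians that answer a comparison, 224 values under alternatives stayed within the main interval, 9 moved beyond it and 1 changed the sign of a median whose interval left out 0. Medians with an interval that included 0, such as that of ribosomal proteins at Day 23, could change sign without entering that last number. For other lists these numbers were 1043, 95 and 4, and for named genes 188, 3 and 0. The podocyte list kept its direction at both days under each setting tried.

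At Day 9, the cholesterol and fatty acid synthesis list went from -0.46 to -0.67 at a mean of at least 50 CPM. The ribosomal protein list went from 0.42 to 0.48 with cells of at least 1000 genes and at most 10% mitochondrial counts, and to 0.48 with median centring. At Day 23, plain CPM gave 0.0522 for the nuclear-encoded respiratory chain (main 0.32), 0.12 for the mitochondrially encoded chain (0.38), -0.17 for ribosomal proteins (0.10) and -0.20 for S phase genes (0.07). Median centring gave 0.11, 0.17, -0.12 and -0.14 for the same lists. These shifts follow from the scaling, since plain CPM moved all genes by 0.27 and centring by 0.21. S phase genes were also at -0.0340 under the stricter cell filter, and the mitochondrially encoded chain was at -0.27 with every deposited barcode. The cause was not tested for these 2 values or for the changes at Day 9. Between days in standard medium, ribosome biogenesis genes went from -0.31 to 0.0176 with median centring, again by the scaling.

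Shares of cells moved more. The podocyte-like share at Day 9 was 4.74% of deprived and 7.25% of standard cells when each library was clustered alone, and 4.77% and 18.4% with every barcode of at least 200 genes, which gave 20.0% for Day 23 deprived cells. Its order between media was the same in each case. The muscle-like share of Day 23 standard cells went from 15.2% to 24.8% at resolution 1.2, 11.9% clustered alone, 24.3% without marked doublets and 21.5% without the highest doublet scores. The Spearman correlation between days went from 0.04 to 0.155 at a mean of at least 50 CPM. The cause was not tested for these shares and correlations.

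Depth limits the Day 23 standard library most, and 20 ratios between media at Day 23 rested on the floor of 3 counts.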

Other observations

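The tests of genes with at least 10 counts due, of clusters led by MYL1 and of mixed-up samples were chosen after results were seen, and the test within skeletal muscle-like cells before. Some genes had at least 30 CPM in both libraries of a day and under 2 CPM in both of the other day: CHCHD2, CNTN4, CRYZ, FOSB, H19, NNAT and TYW3 at Day 23, and CSRP1, FRG1BP, FRG1CP and ZNF667-AS1 at Day 9. The same criterion gave 0 genes between the media and 0 between crossed pairs. CRYZ and TYW3 are neighbours on chromosome 1, so they are not independent.

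A different mixture of cell types is a candidate explanation for these 11 genes. Within skeletal muscle-like cells (310 at Day 23 and 83 at Day 9), 63.6% of them (7 of 11) differed at least 4-fold in the same direction, which decided nothing under the bounds set beforehand. Of the 8 genes for which an equal level would give at least 10 counts, 87.5% (7 of 8) did. Neither test held the mixture constant, since 168 of the 310 cells came from a cluster with PAX7 that the class lacks at Day 9. Within the clusters led by MYL1 (142 and 83 cells), 85.7% of the genes with at least 10 counts due (6 of 7) differed. The 11 genes were chosen for under 2 CPM at the other day. The percentages among genes with at least 10 counts due were thus nearly fixed in advance and do not test mixture. The counts show only that H19 (775 and 0) and CHCHD2 (158 and 0) were seen in cells of the MYL1 clusters at Day 23 and not at Day 9. That argues against mixture as the whole cause for H19 and CHCHD2, and leaves the other genes open. Libraries from other cells than the labelled line may explain the pattern, since a check for mixed-up samples found that 2 of the 4 libraries did not match the labelled line. That check was narrowed to protein-coding genes after a version that included processed pseudogenes had marked all 4. Another origin of cells and a biological effect of day were not told apart and stay open.

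Libraries labelled Day 9 held podocyte-like, muscle-like, neuron-like and endothelial-like cells, the last at 0.508% of deprived and 0.103% of standard cells. At Day 23, the ratio of deprived to standard was lower for processed pseudogenes than for their parent gene in 214 of 244 families (87.7%), by a median log2 difference of -0.87. MT-RNR2 took 7.22% of counts in the Day 9 deprived and 4.78% in the Day 9 standard library, and 5.21% and 1.82% at Day 23. MALAT1 took 3.15% and 0.846% at Day 9, and 2.40% and 1.42% at Day 23.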
